A study of Bos taurus with 10 samples.

How the data were processed

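Total RNA of 10 embryo samples was labelled with Cy3 and hybridised to a 1-colour Agilent bovine oligonucleotide array, 1 array per sample, per the labels. The labels' extraction text speaks of endometrium, while titles, source and tissue fields name embryos; the samples are called embryos here. Groups and replicate numbers came from the sample titles: vehicle (n = 2), 30 nmol/min senktide (n = 4) and 300 nmol/min senktide (n = 4).

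The deposited scanner files hold intensity values per spot, made with Agilent Feature Extraction 11.5.1.1 per the file headers, while the submitters' processing notes name version 10.5.1.1. The authors' processed intensity is background-subtracted and detrended within the array, with a surrogate in place of low values, per the file headers, and was not scaled between arrays. The deposited series matrix holds log2 values, with scale and centring not stated in the labels. Set against the scanner files, it equalled log2 of the processed signal minus each array's 75th percentile over all probes and minus each probe's median, within 0.01 for at least 99.8% of values on each array, so its direction is known. Its column medians were 0.22 and 0.12 (vehicle), 0.045, 0.066, −0.13 and −0.31 (30 nmol/min) and 0.16, −0.18, −0.28 and −0.23 (300 nmol/min). Flags of the deposited files, coded 0 or 1, gave spots well above background and outlier spots, per the file headers; outlier spots were left out, and 0 probe spots were saturated.

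The main values were log2 of the processed signal, averaged over spots of 1 probe, minus the array's 75th percentile. Since fewer than 50% of probes were detected, that percentile was taken over the 2492 probes well above background on all 10 arrays, with all probes as an alternative. Of 43653 probes, 8936 were well above background on at least 2 arrays and were tested; 32459 were so on none. Names came from matching accessions to a RefSeq table of another assembly (ARS-UCD2.0, used for names only), which named 20595 probes by accession, 10745 by symbol, 406 by synonym and 328 by another accession; 2908 kept the file's name and 8671 had none. Coordinates are those of the files (build Btau_3.1 per the file headers). The 7720 named tested probes stood for 5452 genes; for each gene the tested probe with the highest mean was used. A probe not well above background on any array of a group has only a bound there: the brighter group's mean was set against the dim group's mean of the higher of the array's lowest well above background signal and the probe's own, and no fold is given where that is under 1. No value of a named gene is given where neither group compared had at least 2 arrays well above background. The number of arrays limits the precision.

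Each probe was fitted with limma 3.58.1 (lmFit and eBayes, R 4.3.3) with 1 coefficient per group over all 10 arrays, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Group comparisons were 30 nmol/min against vehicle, 300 nmol/min against vehicle, 300 against 30 nmol/min, and both doses pooled against vehicle. Gene lists (29, fixed before the data were examined) were tested with camera at a preset correlation of 0.01, with an estimated correlation and fry beside it; 25 had at least 3 tested genes. The 29 lists were epiblast and pluripotency, trophectoderm, primitive endoderm, cavitation with junctions and fluid transport, Hippo pathway, trophoblast secreted products, interferon-stimulated genes, cholesterol synthesis, fatty acid metabolism, glycolysis, oxidative phosphorylation, antioxidant defence, heat shock and stress, apoptosis, cell cycle, chromatin modifiers, imprinted genes, maternal oocyte transcripts, embryonic genome activation, growth factors, neurokinin and hormone signalling, reference genes, ribosomal proteins, and 6 lists of other cells and Y-linked genes. Array shares were compared with exact two-sided permutation tests. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 read the files and drew the figures.

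The genes named in the text were, per comparison, the 10 higher and 10 lower genes with the largest change among those past the threshold with no overlap of groups, filled by the smallest p where fewer passed; the 4 members with the smallest p of each called list; the first member of any other list that passed adjusted over the list alone; and POU5F1, NANOG, SOX2, CDX2, GATA3, GATA6, IFNT2, TACR3 and XIST. Genes whose identifiers start with LOC were left out of this rule. Some genes that the rule took are not reported here.

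The 10 arrays lay on 3 slides, and slide and scan marked the same arrays, so scan was not run apart from slide. Slides 1 and 2 each held 1 array of every group and slide 3 held replicates 3 and 4 of both senktide groups. Deviations from the group means correlated within same-numbered senktide pairs at r = 0.493, 0.241, 0.444 and 0.322. Different-numbered pairs had r = 0.406 and 0.0896 within slide 3, and 0.401 and 0.124 between slides 1 and 2. These values do not separate pairing by number from slide. The numbers in the titles, which follow the slides, were nonetheless taken to pair the senktide arrays. The first principal component (34.5% of variance) set slide 3 apart.

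The steps were tested on simulated data before use. With changes of 1 and 2 on the log2 scale each set in 100 of 8932 simulated probes, 21% and 75% were called for 30 nmol/min against vehicle, 16% and 60% for 300 nmol/min against vehicle, and 44% and 82% for 300 against 30 nmol/min. For 300 against 30 nmol/min, a list of 20 genes shifted by 0.5 was called in 20 of 20 runs over 5451 genes, and 1 of 480 other lists was. The simulated values held no slide differences and no correlation between genes, so these rates need not hold for the measured arrays.

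Alternatives were quantile normalization, scaling to the median, normexp background correction with an offset of 50, no filter or a filter on all 10 arrays, an intensity trend with robust variances, array weights, only the groups compared, replicate and slide blocks, the series matrix, looser thresholds, the mean of a gene's probes, leaving out each array, and, added after seeing the data, the slide block and the series matrix for lists, scaling to all probes, a common floor, a slide block over probes detected on all arrays, slides 1 and 2 or slide 3 alone, bounds by slide, array and scaling, each dose against its own vehicle array, and simulated unchanged groups with slide differences.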

Results

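Embryos were flushed from superovulated cows on day 7 after the first insemination, and the RNA of 10 embryo samples was measured on 1-colour bovine oligonucleotide arrays. The cows had been infused intravenously with senktide, a peptide agonist of the neurokinin-3 receptor, or with its solvent. Senktide infusions lasted 2 h and began 48 h into superovulation, and insemination took place at 108 and 120 h. The vehicle group held 2 samples, the group infused at 30 nmol/min held 4 and the group infused at 300 nmol/min held 4. The labels do not state whether the samples of a group came from separate cows, or how many embryos each held, so the p-values measure only the spread between these samples, which may be technical. The study asked whether the infusion altered the quality and stage of the embryos.

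The arrays held transcripts known from the trophectoderm and inner cell mass of the blastocyst. KRT8 and KRT18, the paired keratins of the trophectoderm, lay at log2 signals of 4.26 ± 0.27 and 3.54 ± 0.36 (SD, n = 10) relative to each array's scale. The trophectoderm regulators GATA2 (−0.52 ± 0.29), GATA3 (−1.35 ± 0.23) and TFAP2C (−1.42 ± 0.30) and the inner cell mass gene SOX2 (−2.22 ± 0.50) were well above background on all 10 arrays, while TFAP2A, another trophectoderm regulator, was so on 1, a vehicle array. SSLP1, a trophoblast secretory product, was well above background on 10 arrays, and IFNT3, an interferon tau gene, on 9. POU5F1 was well above background on 4 arrays, 2 of each senktide group, all on slide 3, which held no vehicle array. The pluripotency gene NANOG, the trophectoderm gene CDX2 and TACR3, which encodes the receptor that senktide binds, were not well above background on any array. The same held for OVGP1 of the oviduct and uterus, COL1A1 of stroma, HBB of blood and S100A8 of neutrophils. Other genes of the lists for those cells were well above background on some arrays, among them LYZ, a lysozyme of leukocytes, on all 10, and, on no vehicle array, CLU of the uterine epithelium (4 arrays at 30 and 3 at 300 nmol/min), the leukocyte genes PTPRC (2 and 3) and ITGB2 (2 and 2), the globin gene HBA (2 and 2) and COL1A2 of stroma (1 and 2), all named after their values were seen. XIST was well above background on 1 array of each senktide group, both on slide 3. GATA6 and IFNT2 were named on no probe used here.

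The arrays were dim, and brightness differed by slide more than by group. Of 43803 probe spots, 8.31% ± 1.60 (SD, n = 2) were well above background in the vehicle group, 14.5% ± 5.22 (n = 4) at 30 nmol/min and 15.6% ± 4.49 (n = 4) at 300 nmol/min. The differences from vehicle were not past the threshold (exact permutation p = 0.2 and 0.133, two-sided, where 15 arrangements allow no p below 0.0667), nor was that between the doses (exact permutation p = 0.686). Slide 3, which held 4 senktide arrays and no vehicle array, averaged 19.1%, against 10.1% on the 6 arrays of slides 1 and 2. Within slides 1 and 2 the 30 nmol/min array exceeded its vehicle array by 4.36 and −0.667 percentage points, and the 300 nmol/min array did so by 3.30 and 3.72. On slides 1, 2 and 3 the 300 nmol/min arrays differed from the 30 nmol/min arrays by −1.06, 4.39 and 0.413 points.

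**Figure D1:**
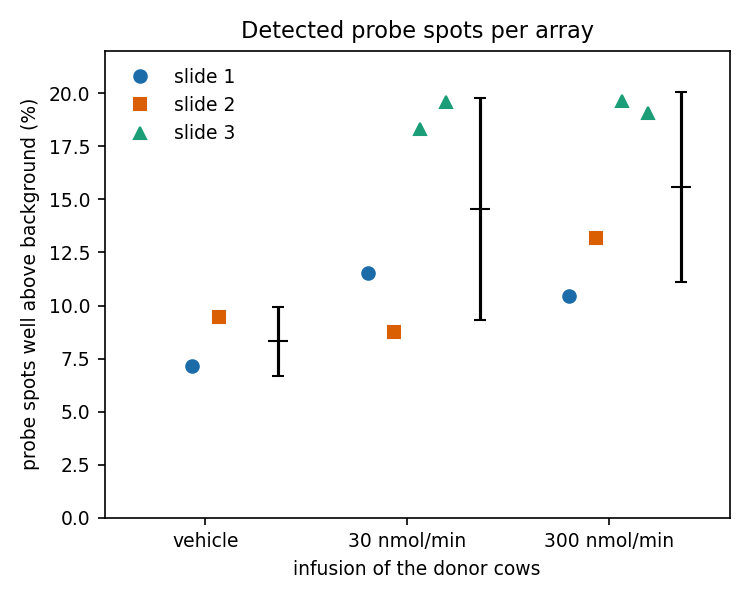
Percent of probe spots well above background (vertical axis, from 0) on each array by infusion group (horizontal axis); marker shape and colour give the slide, and the black bars are group means ± SD (n = 2, 4 and 4). The 4 arrays of slide 3 lie between 18.3% and 19.6%, above all 6 arrays of slides 1 and 2, which lie between 7.17% and 13.2%.

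At 300 nmol/min, 1 probe differed from vehicle past the threshold, a probe of REXO2, an oligoribonuclease that degrades short RNA in mitochondria. It was not well above background on either vehicle array and well above it on all 4 arrays at 300 nmol/min, at a log2 signal of −1.95 ± 0.20 (SD, n = 4), which made it at least 1.97-fold higher. The limma adjusted p of 0.0243 is that of the fitted difference from the measured vehicle signals, and not of this bound. With each vehicle array raised to the higher of its value and its lowest well above background signal, the limma adjusted p was 0.235. A second REXO2 probe, which was well above background on all 10 arrays, lies a short way along the same transcript. It differed by 0.34 (SE 0.25, limma adjusted p = 0.527), so the call rests on 1 of the 2 probes of the gene. The first covers bases 23267223 to 23267282 of chromosome 15 and the second bases 23267296 to 23267355 in the array's genome build, Btau_3.1. REXO2 fell outside the rule for named genes and was chosen after its values were seen. Within slides 1 and 2 the first probe was at least 1.67-fold and 2.92-fold higher. With the measured vehicle signals, the adjusted p was 0.0667 with slide as a block and 0.175 with the replicate number as a block, so both blocks ended the call. The fitted difference, taken from vehicle signals that were not well above background, did not shrink: it was 2.30 (SE 0.24) without a block, 2.40 (SE 0.25) with slide and 2.40 (SE 0.25) with the replicate number, and the call ended because 5 and 4 residual degrees of freedom were left in place of 7. Under the other choices made before the data were examined or added later, its adjusted p ranged from 0.00182 to 0.505.

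Other genes had the smallest p-values at 300 nmol/min without passing the threshold. Here and below, an adjusted p beside a bound is that of the fitted difference and does not test the bound. PTGS2, the inducible cyclooxygenase of prostaglandin synthesis (chromosome 16, bases 65512180 to 65512239), was well above background on all 4 arrays at this dose, at −2.30 ± 0.81, and on neither vehicle array. It was at least 1.54-fold higher (limma adjusted p = 0.10). By the same reckoning TNFRSF21, a death receptor, was at least 1.19-fold higher (adjusted p = 0.10), HMOX2, the constitutive haem oxygenase, at least 1.66-fold (adjusted p = 0.172), MRPL43 of the mitochondrial ribosome at least 1.11-fold (adjusted p = 0.142; 1 of its 2 other probes went the other way), and PLEKHB2, well above background on 2 of 4 arrays, at least 1.05-fold (adjusted p = 0.153). GNPDA1, which returns glucosamine phosphate to glycolysis, was 2.77-fold higher (log2 1.47, SE 0.27, adjusted p = 0.153); 1 of its 2 vehicle arrays was well above background, and 1 of its 3 other tested probes went the other way. Its difference was 2.90 when scaled to the median of all probes and 0.76 with normexp and quantile normalization. Without vehicle replicate 2 no bound was left for TNFRSF21, MRPL43 and PLEKHB2, nor was one within slide 1. Scaled to the 75th percentile of all probes, the bounds of the higher genes ran from 2.36-fold (PLEKHB2) to 4.44-fold (REXO2). TMOD4, an actin filament capping protein, was at least 5.03-fold lower and RESTB at least 9.92-fold lower (adjusted p = 0.172 for each); both were well above background on both vehicle arrays and on none at this dose. These 2 bounds depended on the arrays and the scaling. On slides 1 and 2 alone they were 2.80-fold and 5.37-fold, with 3.13 and 2.95 within slide 1 and 2.51 and 9.76 within slide 2, and scaled to the 75th percentile of all probes they were 2.23-fold and 4.40-fold, and to the median 1.87-fold and 3.69-fold. The fitted differences, taken from signals not above background at this dose, were as small as −0.39 for TMOD4 with a common floor and −1.17 for RESTB with normexp and quantile normalization. The bound of RESTB was 17.3-fold without vehicle replicate 1 and 5.68-fold without vehicle replicate 2. At 30 nmol/min neither of the 2 other tested RESTB probes shared the direction of this one. The RNA-binding or RNA-processing genes PRRC2C (log2 −1.61, SE 0.32) and RSRC2 (−1.32, SE 0.26) and the ankyrin-repeat gene ANKRD17 (−1.52, SE 0.29), each well above background on 1 vehicle array, and MRPS10 (−1.41, SE 0.30) and NUDT16 (−1.36, SE 0.29), a nucleotide hydrolase, were lower with adjusted p = 0.172. When arrays were scaled to the median of all probes, none of these 5 held its size: RSRC2, MRPS10 and NUDT16 turned to 0.10, 0.02 and 0.07, and PRRC2C and ANKRD17 stood at −0.18 and −0.09. Of the 20 genes the rule took for this comparison, 8 had no fold, 5 of them with a positive and 3 with a negative difference, because they were not well above background on either vehicle array and either the bound was under 1 or no array at this dose measured them.

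The lists of embryo and metabolic genes did not shift past the threshold at 300 nmol/min: limma camera called 0 of 25 lists, 4 had an unadjusted p under 0.05, and camera with an estimated correlation called 0. The directional test of fry, which sets a list against no change and not against the other genes as camera does, called 2 lists. Cholesterol synthesis and uptake had the highest median of the 25 lists (0.53, against −0.11 for all genes), with 9 of 13 genes higher and 4 lower (camera adjusted p = 0.131, fry adjusted p = 0.0478). Its members included mevalonate kinase MVK (log2 1.06, SE 0.24, adjusted p = 0.175, well above background on 1 vehicle array; 2.48 when scaled to the median of all probes and 0.54 with normexp and quantile normalization) and MSMO1, which demethylates sterols (1.07, SE 0.44, adjusted p = 0.328, well above background on 1 vehicle array). Of the 13 genes, 1 was well above background on all 10 arrays, SREBF2, the transcription factor of the pathway, at −0.46 (SE 0.23, adjusted p = 0.389). In the Hippo pathway, which restrains YAP and TEAD in the inner cells, 7 of 8 genes were lower (median −0.56, camera adjusted p = 0.371, fry adjusted p = 0.0478). None of the 8 Hippo genes was well above background on all 10 arrays, and the vehicle arrays were the dimmer ones. WWTR1, a partner of TEAD factors that was well above background on 1 vehicle array, stood at −1.41 (SE 0.69, adjusted p = 0.379). MSMO1, SREBF2 and WWTR1 were chosen after their values were seen. Cavitation, junctions and fluid transport had an adjusted p of 0.180 (11 of 19 genes higher, median 0.14), fatty acid metabolism and lipid droplets and glycolysis and pyruvate handling 0.233 each.

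Adjusted over the list alone, 5 genes were higher and 3 lower at 300 nmol/min, while 0 members passed over all probes by limma. The higher ones were PTGS2, HMOX2, MVK, EZH2 and DSC2. EZH2, the histone H3 lysine 27 methyltransferase, was 1.89-fold higher (log2 0.92, SE 0.22, adjusted p = 0.180; 2.34 when scaled to the median of all probes and 0.39 with normexp and quantile normalization), with 1 vehicle array well above background and 1 of its 3 other probes going the other way. DSC2, a desmosomal cadherin, had no fold because neither vehicle array was well above background and no bound above 1 could be set. The lower ones included ACAT2 of acetoacetyl-CoA synthesis, well above background on 1 vehicle array and 1 array at this dose, and CCNE1, the cyclin of S phase entry, which had no fold for the same reason as DSC2. The trophectoderm and inner cell mass markers GATA3 (−0.08, SE 0.25) and SOX2 (−0.35, SE 0.43) differed by less than the spread (adjusted p = 0.894 and 0.715), and the direction of each turned under other scalings.

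**Figure D2:**
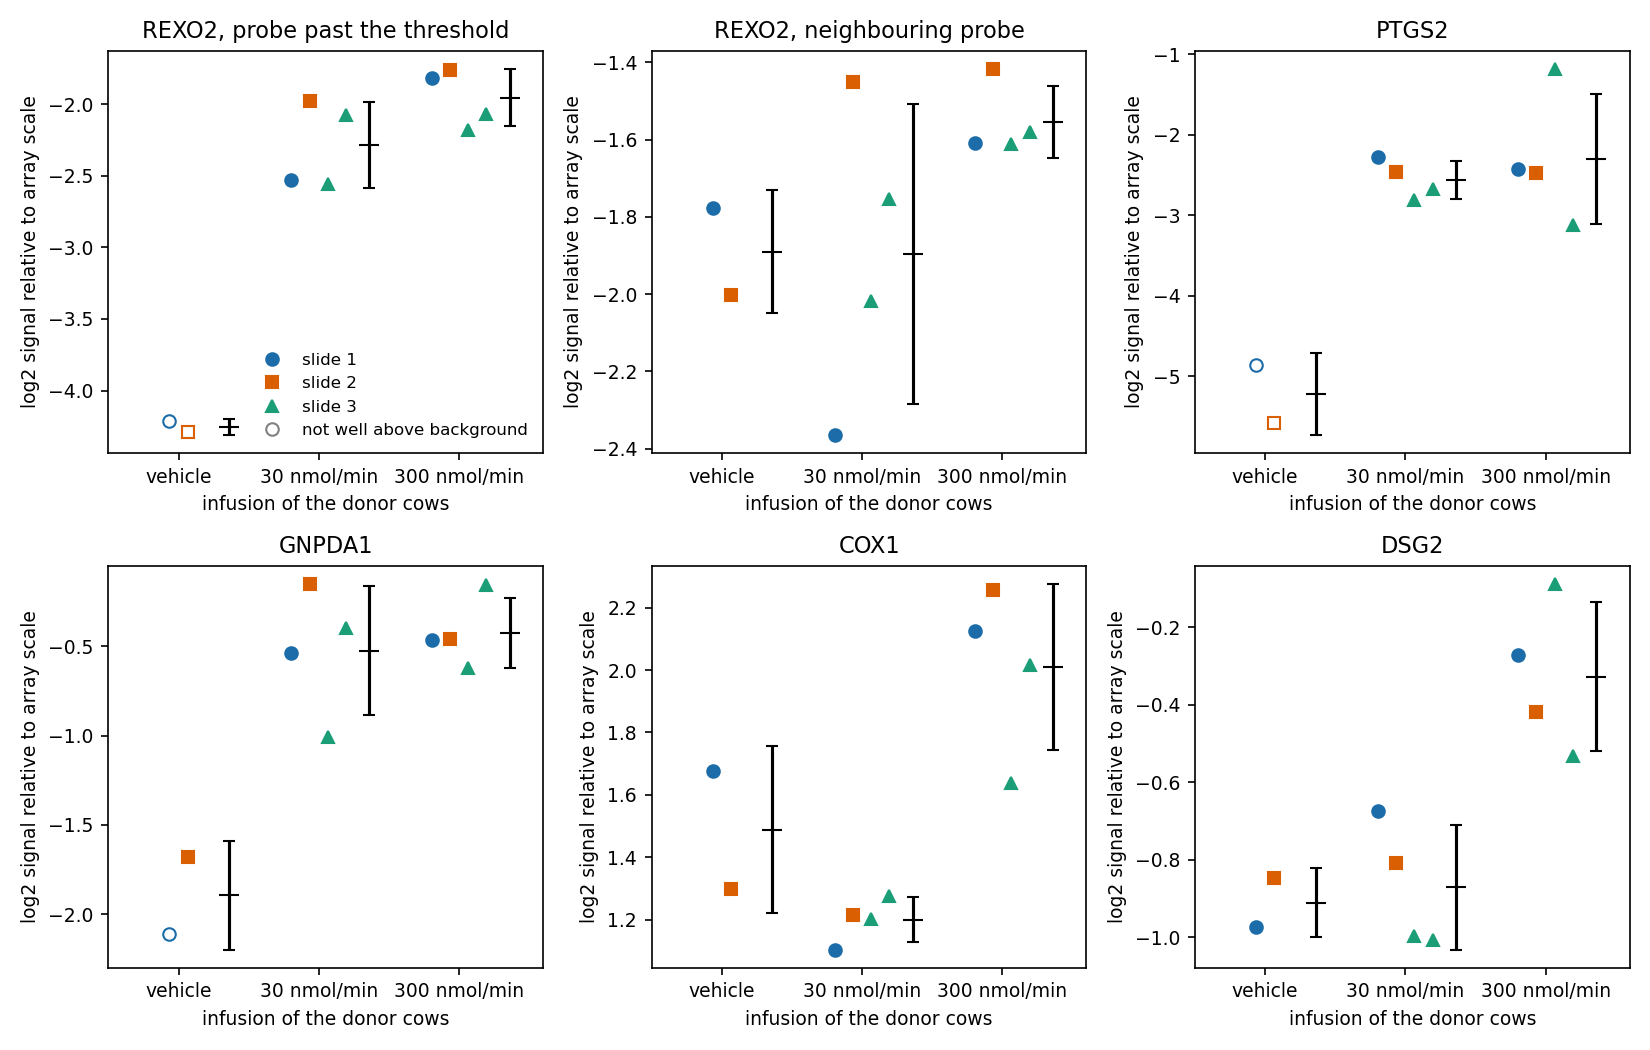
Log2 signal relative to each array's scale (vertical axis, range differing between panels) by infusion group (horizontal axis) for the REXO2 probe that passed the threshold, its neighbouring probe, PTGS2, GNPDA1, COX1 and DSG2. Points are arrays, open where not well above background, with shape and colour by slide; black bars are group means ± SD (n = 2, 4 and 4). The first REXO2 probe and PTGS2 are not well above background on either vehicle array, while the neighbouring REXO2 probe lies at −1.89 there and at −1.90 and −1.55 with senktide.

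At 30 nmol/min, limma found 0 probes past the threshold against vehicle, with 1006 at an unadjusted p under 0.05 (441 higher, 565 lower; 446.8 expected by chance). The smallest adjusted p was 0.0728, at the same REXO2 probe (at least 1.56-fold higher, and 1.02-fold and 2.51-fold within slides 1 and 2), while the second REXO2 probe stood at −0.01 (SE 0.25). PTGS2 was at least 1.29-fold higher (adjusted p = 0.184), HMOX2 at least 1.55-fold (adjusted p = 0.206), MRPL43, well above background on 3 of 4 arrays, at least 1.06-fold (adjusted p = 0.184), and GNPDA1 was 2.59-fold higher (log2 1.37, SE 0.27, adjusted p = 0.184). Without vehicle replicate 2 no bound was left for PTGS2 and MRPL43, and within slide 1 none for MRPL43; scaled to the 75th percentile of all probes the bounds of REXO2, PTGS2, HMOX2 and MRPL43 were 3.26, 2.69, 3.23 and 2.20-fold. RESTB was at least 8.65-fold lower (adjusted p = 0.204), although neither of its 2 other tested probes shared its direction. Its bound was 4.29-fold on slides 1 and 2 alone, 3.14-fold and 5.87-fold within each, 15.1-fold without vehicle replicate 1, 4.95-fold without vehicle replicate 2, and 4.16-fold or 3.46-fold when scaled to the 75th percentile or the median of all probes, and its fitted difference, taken in the same way, was −1.14 with normexp and quantile normalization. RASSF1, a tumour suppressor of the Hippo network (−1.24, SE 0.24, adjusted p = 0.184), ZNF205, a zinc finger gene (−1.21, SE 0.25, adjusted p = 0.204), RSRC2 (−1.45, SE 0.26), PRRC2C (−1.51, SE 0.32) and ANKRD17 (−1.44, SE 0.29) were lower without passing the threshold. Under scaling to the median of all probes RASSF1 and ZNF205 turned to 0.08 and 0.11, RSRC2, PRRC2C and ANKRD17 stood at −0.13, −0.19 and −0.12, and GNPDA1 at 2.69, against 0.78 with normexp and quantile normalization. Of the 20 genes the rule took, 11 had no value to give. GATA3 stood at 0.07 (SE 0.25) and SOX2 at −0.18 (SE 0.43).

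No list shifted at 30 nmol/min (camera 0 of 25, with 2 at an unadjusted p under 0.05; estimated correlation 0; fry 0). Those 2 were cholesterol synthesis, with 9 of 13 genes higher (median 0.41, adjusted p = 0.569), and the Hippo pathway, with 8 of 8 lower (median −0.46, adjusted p = 0.569). Adjusted over the list alone, PTGS2 and HMOX2 were higher and 2 genes lower, ACAT2 and SSLP1. SSLP1, named after its values were seen, lay at −1.23 ± 0.13 (SD, n = 4) against −0.60 ± 0.13 (n = 2) in the vehicle group (log2 −0.63, SE 0.18, adjusted p over all probes 0.308).

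At both doses the comparisons with vehicle had more small p-values than the 446.8 expected without structure among the arrays. Pairs of senktide arrays, set against all other arrays with slide as a block, gave 555 to 768 such probes. At 300 nmol/min 1233 probes had an unadjusted p under 0.05 (525 higher, 708 lower), against 446.8 expected. The direction of these depended on the scaling. On every array the 75th percentile of all probes lay below the lowest signal well above background. The percentile was a processed signal of 6.84 to 9.25, and that lowest signal 9.47 to 14.9. The median of all probes was lower still, at 3.15 to 4.12. Scaling to either thus rests on spots that were not well above background. Scaled to the 75th percentile of all probes, 1315 were higher and 20 lower at 300 nmol/min and 832 higher and 13 lower at 30 nmol/min, and the median of all tested probes moved from −0.11 to 1.06 and from −0.11 to 0.95. Quantile normalization gave 1473 higher and 246 lower at 300 nmol/min, and 1238 and 206 at 30 nmol/min. Normexp with quantile normalization gave 1297 and 477, and 1038 and 405, and scaling to the median of all probes gave 1414 and 3, and 934 and 2. On slides 1 and 2 alone, 699 probes had an unadjusted p under 0.05 at 300 nmol/min and 491 at 30 nmol/min.

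Pooling both doses against vehicle called 3 of 8936 probes by limma, 2 higher and 1 lower, each named after its values were seen. At an unadjusted p under 0.05, 544 were higher and 783 lower, against 1503 and 19 when scaled to the 75th percentile of all probes. The REXO2 probe was higher with an adjusted p of 0.0210. A probe with no gene name on chromosome 15 (bases 26291630 to 26291689) was higher with a pooled adjusted p of 0.0338. By dose its limma adjusted p was 0.0728 at 30 and 0.0642 at 300 nmol/min, past the threshold at neither. It was well above background on all 8 senktide arrays and neither vehicle array. Its bounds, which these p-values do not test, were 1.43-fold higher at 30 and 1.37-fold at 300 nmol/min, with none left within slide 1 at 300 nmol/min. Scaled to the 75th percentile of all probes the bounds were 2.97-fold and 3.08-fold. The third, a probe of NONO, a paraspeckle protein that binds RNA and DNA (adjusted p = 0.0338), was not well above background on either vehicle array and was so on 2 arrays of each senktide group, so no change in its level was measured. The NONO probe that was well above background on all 10 arrays differed by 0.38 (SE 0.22, adjusted p = 0.418), while another tested one, also not well above background on either vehicle array, had a fitted difference of the same sign as the called probe (adjusted p = 0.228), which is likewise no measured change. With slide as a block 4 probes passed, REXO2 with an adjusted p of 0.0416 among them; with the replicate number as a block 0 did, by limma, with 1097 at an unadjusted p under 0.05. Quantile normalization called 223 probes, 213 higher and 10 lower.

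The changes of the 2 doses against vehicle were correlated across genes, which are not independent replicates (Pearson r = 0.890, covariance 0.369, 5451 genes, 83.7% with the same sign). Unchanged groups were simulated with 1 simulated vehicle group shared by both doses, every array being drawn from each gene's residual spread. They gave r = 0.665 (SD 0.016), a covariance of 0.159 and 73.2% with the same sign, so the covariance exceeded the simulated one by 0.209. That simulation covers the sharing of a vehicle group, but neither traits of the measured vehicle arrays nor the shared slides. With the slides' fitted differences added, which hold noise of their own, it gave r = 0.835 (SD 0.0065), a covariance of 0.219 and 80.5% with the same sign, and the excess in covariance was 0.150. The 2 vehicle arrays are too few to divide into groups of 2, and part of the excess may come from the shared controls. With each dose set against its own vehicle array, in both orders, r was 0.440 and 0.408 and the covariance 0.237 and 0.220, with the slides still shared. On slides 1 and 2 alone r was 0.632 and the covariance 0.181, against 0.499 (SD 0.017) and 0.116 for unchanged groups simulated there. Across genes, the difference of both doses from vehicle on slide 1 correlated with that on slide 2 at r = 0.0528, or 0.160 over probes well above background on all 10 arrays.

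Between the doses, camera at its preset correlation called 1 list higher at 300 than at 30 nmol/min, a call that ended under several of the other choices given below. The list of cavitation, junctions and fluid transport genes rose (limma camera adjusted p = 0.0208), with 13 of 19 genes higher and 6 lower, a median difference of 0.09 and a mean of 0.20; the adjusted p = 0.578 with an estimated correlation. Its members with the smallest p were of desmosomes, the junctions that hold the trophectoderm together, and of the sodium pump that fills the blastocoel. The cadherins DSG2 (log2 0.54, SE 0.16) and DSC2 (0.89, SE 0.33, well above background on 2 arrays at the lower dose), the plaque protein DSP (0.82, SE 0.36) and the pump subunit ATP1B3 (0.37, SE 0.18) each had an adjusted p of 1.00 over all probes. DSP stood at 0.35, 1.75 and 0.59 on slides 1, 2 and 3 and at 0.43 without replicate 2 at 30 nmol/min, ATP1B3 at 0.04, 0.51 and 0.46 on the slides, and normexp with quantile normalization put DSC2 at 0.26 and ATP1B3 at 0.15. The adherens junction cadherin CDH1 stood at 0.33 (SE 0.18) and the water channel AQP3 at −0.07 (SE 0.19), both chosen after their values were seen. Over the 11 members well above background on all 10 arrays the median was 0.05, with 8 higher and 3 lower. Relative to all genes the list's median was higher by 0.11, 0.43 and 0.08 on slides 1, 2 and 3, and its adjusted p was 0.0572 with slide as a block, which ended the call, and 0.0397 with the replicate number as a block, which kept it. The call also ended without any of 4 arrays, replicates 2 and 4 at 30 nmol/min (adjusted p = 0.102 and 0.0848) and replicates 1 and 3 at 300 nmol/min (0.0812 and 0.133). Camera called 1 of 25 lists here (3 at an unadjusted p under 0.05), while camera with an estimated correlation and fry each called 0.

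No probe differed between the doses past the threshold (limma, smallest adjusted p = 0.746), and 269 had an unadjusted p under 0.05, 150 higher and 119 lower, fewer than the 446.8 expected. Scaled to the 75th percentile or the median of all probes, 23 were higher and 3 lower, or 16 and 2. With the replicate number as a block 1 probe passed, and 447 had an unadjusted p under 0.05. Among genes with the smallest p, COX1, the mitochondrially encoded cytochrome oxidase subunit, was 1.75-fold higher at 300 nmol/min (log2 0.81, SE 0.18), with group values that did not overlap. KLF6, a zinc finger transcription factor (0.67, SE 0.15), and EIF4A2, a translation initiation helicase (0.77, SE 0.18), were higher in both or all of their tested probes. DDIT3, the stress factor CHOP (1.22, SE 0.36), was well above background on 2 and 3 arrays, HP1BP3, a heterochromatin protein, stood at 1.11 (SE 0.32), and OXSM of mitochondrial fatty acid synthesis, well above background on 1 and 2 arrays, at 0.99 (SE 0.27). CD81, the tetraspanin (−0.80, SE 0.23), NT5C, a nucleotidase (−0.66, SE 0.19), EGR1, an immediate early transcription factor (−1.36, SE 0.39), PRXL2B (2.01-fold, SE 0.28 on the log2 scale), THAP3 (−1.04, SE 0.30), PSPH of serine synthesis (−0.72, SE 0.23) and STT3B of protein glycosylation (−0.52, SE 0.17) were lower; the other tested probe of STT3B went the other way. EGR1, THAP3 and PSPH were well above background on 2 of 4 arrays at each dose, PRXL2B on 2 at 30 and 1 at 300 nmol/min, HP1BP3 on 2 and 3, and NT5C on 4 and 2, so their values rest in part on signals not above background. Under the other choices of processing or arrays, the smallest differences were 0.05 for DDIT3, 0.20 for HP1BP3, 0.13 for OXSM and 0.32 for KLF6. They were −0.12 for EGR1 and −0.11 for STT3B, against 0.59 for COX1, 0.56 for EIF4A2 and −0.58 for CD81. INTS5 of the integrator complex was at least 1.06-fold lower and CDKN2AIP at least 1.03-fold higher, with no bound left for either within slide 1 or 2. All of these had an adjusted p of 1.00, and 3 of the 20 genes the rule took had no fold. GATA3 (−0.15, SE 0.20), SOX2 (−0.16, SE 0.35) and POU5F1 (−0.28, SE 0.34) differed by less than their spread. POU5F1 was well above background only on slide 3, where it stood at 0.46. Adjusted over the list alone, 0 members of any list passed by limma.

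Lists of cell identity and of other cells gave no call in any of the 3 comparisons. Epiblast and pluripotency genes (8 tested) had camera adjusted p-values of 0.569, 0.853 and 0.255 for 30 nmol/min against vehicle, 300 nmol/min against vehicle and 300 against 30 nmol/min; in the last 7 of 8 were lower. Trophectoderm genes (11 tested) had 0.569, 0.853 and 0.764, primitive endoderm genes (10) 0.643, 0.853 and 0.840, and trophoblast secreted products (6) 0.638, 0.800 and 0.379. Oxidative phosphorylation genes (74 tested) were lower in 54 at 300 against 30 nmol/min (median −0.07, adjusted p = 0.151), and ribosomal proteins (75) were higher in 45 (median 0.04, adjusted p = 0.255). The heat shock and stress list (33 tested) had adjusted p-values of 0.569, 0.800 and 0.764, apoptosis and p53 targets (15) 0.569, 0.853 and 0.764, and cell cycle and DNA replication (39) 0.604, 0.853 and 0.764. Antioxidant defence (22 tested), chromatin modifiers (16), imprinted genes (7), maternal oocyte transcripts (3), embryonic genome activation (3), growth factors and receptors (7), neurokinin and reproductive hormone signalling (3), interferon-stimulated genes (8) and reference genes (15) had no adjusted p under 0.255. Of other cells, leukocyte genes (5 tested) had medians of −0.54, −0.48 and 0.06 (adjusted p = 0.569, 0.853 and 0.764), and cumulus and granulosa genes (3 tested) of −0.61, −0.29 and 0.32 (0.604, 0.869 and 0.255). Uterine epithelium (1 tested gene), uterine stroma, muscle and vessel (2) and blood and sperm (2) had too few tested genes for camera, and 0 of 7 Y-linked genes named on the array were tested.

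**Figure D3:**
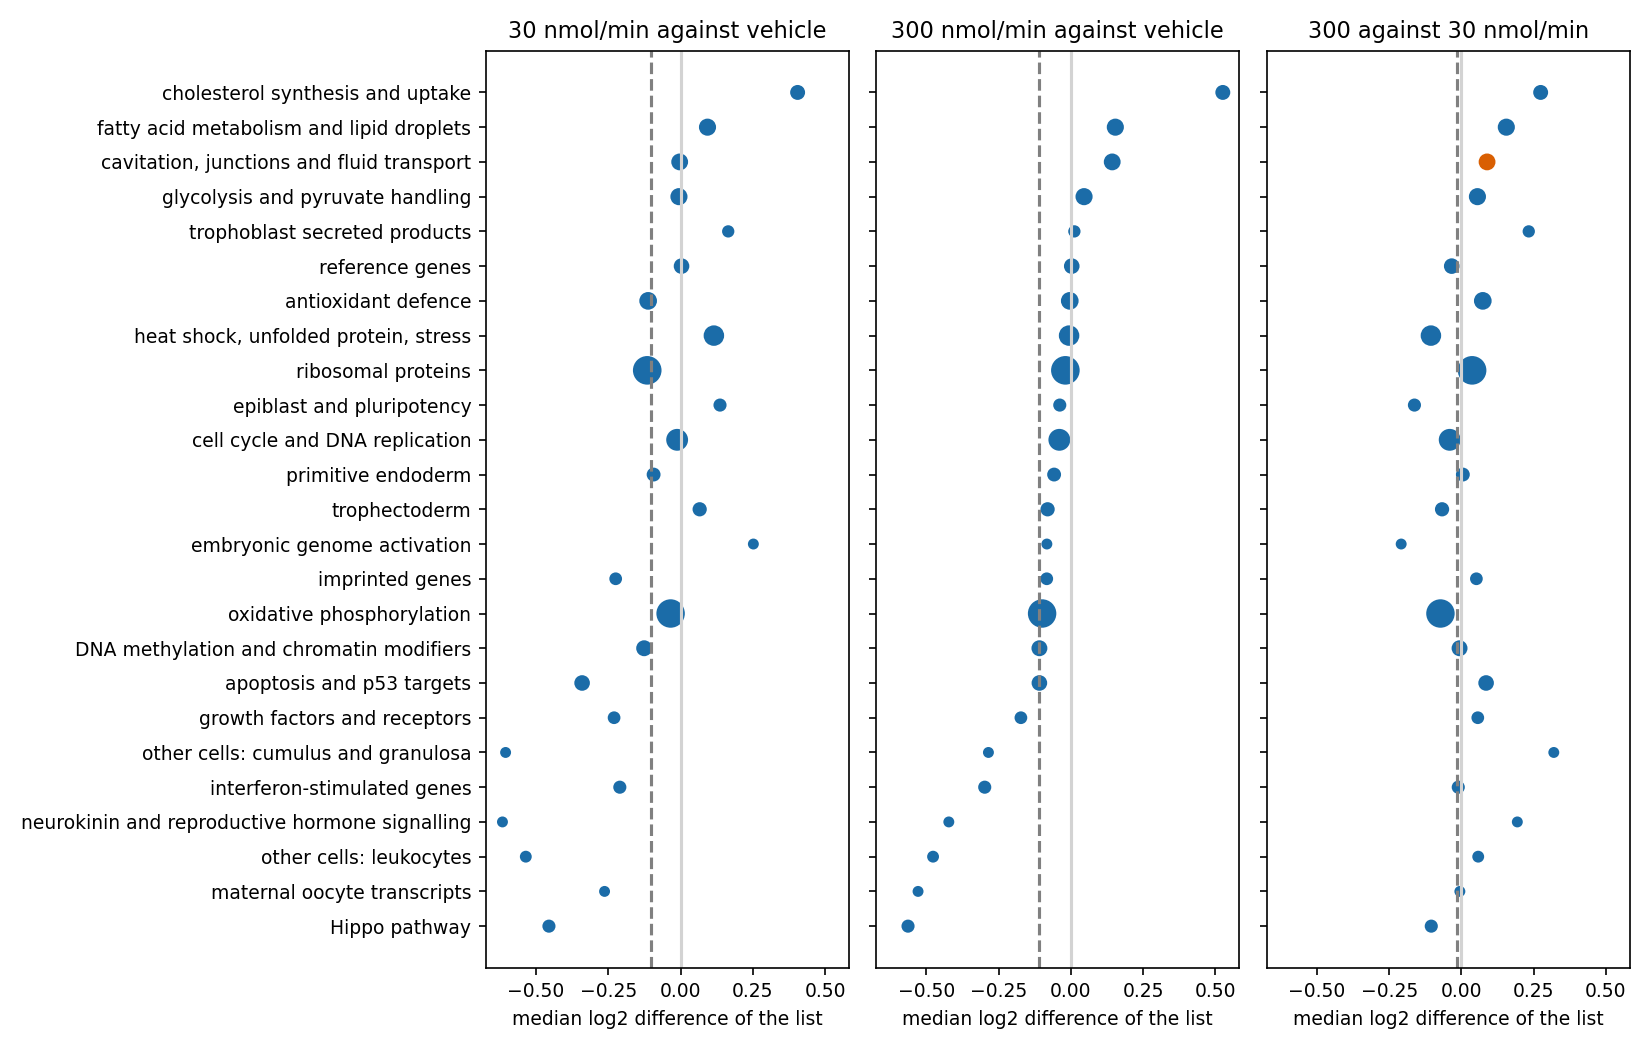
Median log2 difference of the tested genes of each list (horizontal axis) for the 25 lists tested (vertical axis) in the 3 comparisons; point area grows with the number of tested genes, the dashed line is the median of all genes, the solid line is 0, and the orange point marks an adjusted p under 0.05 by camera. That point is the cavitation and junction list at 300 against 30 nmol/min, with a median of 0.09.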

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

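The tests on the REXO2 probes, on the correlation and slides of the junction list and on its own call in the splits, on slide 3 and dim probes, and on the splits' unadjusted counts were chosen after the results were seen; the splits' counts of called lists and the choices of reference arrays were set before those counts were seen. Across 41 sets of 4 arrays (detected shares, named genes measured on all 4 arrays, the REXO2 probe and the junction list's mean), 0 had an array beyond Dixon's limit for 4 values, where chance would give about 1 in 20.

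The REXO2 probe that passed the threshold against vehicle was well above background on neither vehicle array and on all 8 senktide arrays. Its lowest senktide signal was −2.55, while the lowest well above background signal of vehicle replicate 1 was −2.56. A whole-transcript change of log2 1 or more is argued against, under the main scaling only, by the neighbouring probe. It was well above background everywhere and differed by 0.34 (SE 0.25) at 300 nmol/min, below 1 by more than its error. Scaled to the 75th percentile of all probes, the median difference of all tested probes moved from −0.11 to 1.06, so the argument does not carry over. With vehicle at its bound the first probe differed by 0.977 (SE 0.278), so a smaller change of the whole transcript stays open. Slide as the whole cause was tested with slide as a block. Each vehicle array was raised to the higher of its value and its lowest well above background signal. Both doses then lay 0.910 (SE 0.285) above vehicle, with a limma adjusted p of 0.240 over all probes. The 4 within-slide differences ranged from 0.0245 on slide 1 to 1.55 on slide 2. That test cannot decide, because the probe was chosen for its small p in these same arrays. A sequence variant under the probe in the embryos or a transcript form that differs between the groups may account for the pattern. Neither was tested, since no sequence was used here, and an effect of senktide on such a form stays open.

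The junction list, higher at 300 than at 30 nmol/min, may rest on genes that vary together: with an estimated correlation its adjusted p was 0.578. Chance cannot be excluded, because 22 of the 35 splits of the 8 senktide arrays into sets of 4 called at least as many lists as the real split (1), with up to 6 in another split; among the 8 splits that part all same-numbered pairs, up to 4 lists were called. The junction list itself was called in 4 of the 35 splits, with a p as small as the real one in 2 (the real split included), and among those 8 in the real split alone (0.114 in the next), where 8 are too few for a share under 0.05. A source in 1 slide cannot be told apart from a shift on all of them: the shift was 0.434 on slide 2, beyond 2 SD of random lists of the same size (SD 0.161), but 0.114 on slide 1 (SD 0.107) and 0.0796 on slide 3 (SD 0.0793). The dose itself stays open as an explanation.

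More probes had small p-values against vehicle than the 446.8 expected without structure among the arrays. The lack of a vehicle array on slide 3 does not account for all of it with slide as a block, where 1275 probes had an unadjusted p under 0.05 at 300 and 1069 at 30 nmol/min, against 446.8 expected; on the 6 arrays of slides 1 and 2 alone 699 and 491 did, the latter close to chance. Nor do dim probes, since among probes well above background on all 10 arrays 15.6% did. Whether any 2 arrays of slides 1 and 2 would stand apart as far cannot be told apart from an effect of the infusion: the vehicle pair gave 1266 probes against the rest, another of the 9 choices of 1 array per slide, holding 1 vehicle array, gave 1642, making 2 choices as large, and 9 choices are too few for a share under 0.05. The 4 choices without a vehicle array gave 555 to 768. The choice with 1642 held the least detected array of each slide, at 7.17% and 8.77% of spots. Over probes well above background on all 10 arrays that choice gave 308 and the vehicle pair 381, the most of the 9.

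Between the doses 0 probes passed the threshold by limma, a count that no split can go below, so the 269 at an unadjusted p under 0.05 were compared. Chance cannot be excluded, since 19 of the 35 splits gave at least as many. The highest was 2334, in the split that sets slide 3 against slides 1 and 2, where 1257 passed the threshold, which points to slide as a structure of the arrays; with slide as a block 0 passed, with 498 at an unadjusted p under 0.05. Among the 8 splits that part all pairs, which are too few for a share under 0.05, the real one had the most, with 239 in the next.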

How the results depend on the processing

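The common floor, scaling to the 75th percentile of all probes, slides 1 and 2 alone, slide 3 alone, the slide block over probes detected on all arrays and, for lists, the slide block, the series matrix and detection on all arrays were chosen after the results were seen, as were the bounds by slide, array and scaling and the simulations with slides. The cause was not tested for any changed result below unless fewer probes or arrays are named. Scan was not run as a block because it marked the same arrays as slide. Signal limits these arrays: at most 19.6% of spots were well above background. Scaling to the median or the 75th percentile of all probes, and the series matrix, thus rest on spots that were not.

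At 30 nmol/min against vehicle (0 by limma) there were 107 with quantile normalization, 36 with normexp and quantile normalization, 5 with an intensity trend and robust variances and 26 with a common floor; an adjusted p under 0.10 gave 3, an unadjusted p under 0.05 gave 1006, and 442 of these were at least 2-fold. At 300 nmol/min (1) the same choices gave 145, 107, 7, 26, 3, 1233 and 588. It was 0 with scaling to the median, no filter, detection on all 10 arrays (which leaves out the REXO2 probe), array weights, only the arrays compared, the series matrix, all probes for scaling, and slides 1 and 2. For both doses (3) these gave 223, 178, 12, 43, 14, 1327 and 526; the count was 0 with scaling to the median, no filter, detection on all 10 arrays, with or without the slide block, array weights, and slides 1 and 2, and 1 with the series matrix and with all probes for scaling. Between the doses (0) it was 1 with normexp, 269 at an unadjusted p under 0.05, and 34 of these at least 2-fold.

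With the replicate number as a block, the pairing taken from the titles, the counts were 0 at 300 nmol/min, 0 for both doses and 1 between the doses. This block changed no other count of probes or lists. With slide as a block they were 0 at 300 nmol/min and 4 for both doses.

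Lists called at 30 nmol/min (0) were 1 with quantile normalization, with normexp, and with detection on all 10 arrays with or without the slide block. At 300 nmol/min (0) they were 2 with fry, quantile normalization and normexp, and 1 with detection on all 10 arrays with or without the slide block and with the common floor. Between the doses (1) they were 0 with an estimated correlation, fry, the mean of a gene's probes, scaling to the median, the slide block, the series matrix, all probes for scaling and the slide block over detected probes, 2 with quantile normalization, and 3 with normexp, detection on all 10 arrays and the common floor. The junction list stayed higher in all of these. Its adjusted p was 0.578 with an estimated correlation, 0.692 with fry, 0.0665 with the mean of probes, 0.135 with scaling to the median, 0.0572 with the slide block (0.0397 with the replicate block), 0.140 with the series matrix and with all probes for scaling, 0.0580 with the slide block over detected probes, 0.132 on slides 1 and 2, and 0.356 on slide 3.

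The correlation of the doses' changes was 0.821 over probes detected on all 10 arrays, 0.914 with quantile normalization and 0.632 on slides 1 and 2.

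Leaving out each array in turn gave 0 to 36 probes at 30 nmol/min, 0 to 50 at 300 nmol/min, 0 to 61 for both doses and 0 to 0 between the doses. Without vehicle replicate 1 these were 34, 32 and 37, and without vehicle replicate 2 36, 50 and 61; the lone vehicle array is then assumed to vary like the other groups. At 300 nmol/min 0 probes passed without replicate 1, 3 or 4 at 30 nmol/min or any of replicates 1 to 4 at 300 nmol/min. For both doses 0 passed without replicate 4 at 30 or replicate 1 or 4 at 300 nmol/min, and 1 without replicate 1 or 2 at 30 nmol/min. Lists between the doses ranged from 0 to 2, being 0 without replicate 4 at 30 or replicate 1 or 3 at 300 nmol/min and 2 without replicate 3 at 30 nmol/min; at each dose against vehicle they were 0 to 0. The junction list's adjusted p ranged from 0.00927 to 0.133 and the correlation of the doses from 0.838 to 0.933. The detected share between the doses ranged from −0.884 to 2.74 points, being −0.884 without replicate 2 at 30 nmol/min and −0.307 and −0.125 without replicates 3 and 4 at 300 nmol/min.

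Some named genes turned direction. Scaled to the median, RASSF1 stood at 0.082, SOX2 at 1.14 and ZNF205 at 0.11 at 30 nmol/min, and GATA3 at 1.35, MRPS10 at 0.016, NUDT16 at 0.066, RSRC2 at 0.10 and SOX2 at 1.08 at 300 nmol/min. With the series matrix or all probes for scaling, SOX2 stood at 0.88 at 30 nmol/min, and GATA3 at 1.09 and SOX2 at 0.83 at 300 nmol/min. Normexp put GATA3 at −0.060 at 30 nmol/min, and array weights put GATA3 at 0.019 at 300 nmol/min and POU5F1 at 0.060 between the doses. The replicate block and both slide blocks put GATA3 at −0.0068 and SOX2 at 0.18 at 30 nmol/min and SOX2 at 0.020 at 300 nmol/min. Slides 1 and 2 put SOX2 at 0.084, 0.12 and 0.037 at 30, at 300 and between the doses, and slide 3 put GATA3 at 0.16 and POU5F1 at 0.46 between the doses. Leaving out 1 array, GATA3 ranged from −0.19 to 0.32 at 30 and from −0.33 to 0.17 at 300 nmol/min, with −0.19 without vehicle replicate 1, and 0.17 and 0.029 without vehicle replicate 2 and without replicate 2 at 300 nmol/min. SOX2 ranged from −0.52 to 0.16 at 30 nmol/min, with 0.16 without vehicle replicate 1 and 0.021 without replicate 3 at that dose. Between the doses it ranged from −0.40 to 0.12, with 0.12 without replicate 3 at 300 nmol/min. Of 56 gene results, 51 kept their direction and side of the threshold with the replicate block, 52 with the slide block and 41 with quantile normalization, where the other 15 came to pass the threshold.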

Other observations

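The mitochondrial transcripts were singled out, and their tests chosen, after the values were seen. Mitochondrially encoded RNA had a lower mean at 30 than at 300 nmol/min under the 4 scalings run, while its direction against vehicle depended on the scaling. The mean log2 signal of 8 such genes, coding for subunits of the respiratory chain and of ATP synthase, was 1.38 ± 0.047 (SD, n = 4) at 30 nmol/min, 1.76 ± 0.18 (n = 4) at 300 nmol/min and 1.78 ± 0.31 (n = 2) with vehicle. The doses differed by 0.39 (exact permutation p = 0.0286, two-sided, the smallest that 70 arrangements allow), and by 0.56, 0.47 and 0.26 on slides 1, 2 and 3. That test lets arrays change places across slides; over the 4 same-numbered pairs, all 4 higher at 300 nmol/min under each scaling, the exact permutation p was 0.125, the smallest that 16 arrangements allow, so a paired test cannot pass the threshold. The 30 nmol/min group differed from vehicle by −0.40 (exact permutation p = 0.0667, the smallest that 15 arrangements allow), and by −0.30 with quantile normalization (exact permutation p = 0.0667), but by 0.65 with the 75th percentile of all probes (exact permutation p = 0.4) and 0.92 with the median of all probes (exact permutation p = 0.333). The differences between doses were uneven, at 0.81 for COX1, 0.75 for CYTB, 0.58 for ATP6 and 0.34 for COX3, but 0.02 for COX2, the brightest, and −0.01 for ND5. Of 34 mitochondrial probes well above background on all 10 arrays, 32 were higher at 300 than at 30 nmol/min. Between the doses quantile normalization gave a difference of 0.34 (exact permutation p = 0.0286), the 75th percentile of all probes 0.50 (exact permutation p = 0.4) and the median of all probes 0.49 (exact permutation p = 0.486). No adjustment was made for the other gene groups that could have been singled out.

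Of the nuclear-encoded oxidative phosphorylation genes, 20 of 74 were higher and 54 lower at 300 than at 30 nmol/min, with a median of −0.07. The list was not called (camera adjusted p = 0.151). Relative to all genes its median stood at −0.051, 0.162 and −0.156 on slides 1, 2 and 3, so its direction differed between slides.

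Non-overlapping values were common against vehicle. All 4 arrays at 300 nmol/min lay above both vehicle arrays for 823 of 8936 probes and below both for 1451. At 30 nmol/min 682 lay above both and 1061 below both. For a probe exchangeable across slides, 13.3% would separate either way by chance, but slide 3 held no vehicle array. Background alone separated vehicle from 300 nmol/min. Relative to each array's scale, the median spot lay at −4.44 and −5.04 with vehicle and at −5.17 to −7.06 at 300 nmol/min. Probes near background thus tend to fall below both vehicle arrays. The direction of probes with small p-values also depended on the scaling. Between the doses 138 were higher and 103 lower without overlap, where chance gives 2.86%.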
